A study of Mus musculus with 4 samples.

How the data were processed

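RNA was measured in V6.5 mouse embryonic stem cells, in 2 uninduced libraries (0 h) and 2 libraries collected after 24 h of doxycycline, which switches on Cas9 in stable lines carrying guides against Klf genes. The libraries came from a stranded mRNA kit read as single 50 nt reads, per the labels' protocols. The deposited values are raw read counts per Ensembl gene, as the authors made them. TopHat2, HTSeq, DESeq and the genome build mm10 are named, with no versions or roles, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of genes that overlap, on either strand, can therefore not be told apart.

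The table held 45706 genes, of which 19033 had 0 counts in every library. Symbols, coordinates, transcript lengths and GC content came from GENCODE M21 on GRCm38, the assembly that mm10 also names. No match was found for 563 gene identifiers, which held 0.107% of the counts. Total counts were 52412844 and 48838606 at 0 h (replicates A and B), and 48599693 and 46031578 at 24 h. A count of 0 in these libraries allows a level of up to 0.0572 to 0.0652 CPM (3 counts of the total), which covers counting error only.

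Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18005. Libraries were scaled by TMM, and the groups were compared with edgeR 4.0.16's quasi-likelihood test (legacy=TRUE, 2-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM (counts scaled to a common library total) were computed here from the deposited counts with TMM scaling, given as mean ± SD over 2 libraries. The letters A and B were not used as a block, because no label says that a letter marks a shared clone. With 2 libraries per group, the test's precision rests on pooling the spread over genes. The test's p-values for single genes measure only the spread between these samples, which the labels call biological replicates.

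Gene lists (20 primary and 8 background) were fixed before the data were examined, as were the main test, the alternatives and the rule for the genes named. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 28 lists. Beside it stand camera with an estimated correlation and fry. Camera compares a list's genes with the other genes. With the preset correlation it takes its degrees of freedom from the genes, so those p-values do not measure the spread between libraries. The genes named are Klf2, Klf4 and Klf5, then the 10 highest and 10 lowest log2 fold changes among genes past the test with a mean of at least 5 CPM and groups that do not overlap, then up to 4 members of each primary list and 3 of each background list in order of p. Of the genes this rule names, 1 is not reported here. Other genes are said to be chosen after their values were seen.

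Tested on simulated data drawn from the libraries' means and sizes (17702 genes run), the main test recovered 2% of genes changed 1.25-fold, 26% at 1.5-fold, 76% at 2-fold and 100% at 4-fold, with 8 false calls among 110. With no gene changed it made 0 calls. These simulations drew genes independently, gave both groups the same spread and held no GC trend. The SD of log2 differences between the real replicates was 0.356 at 0 h and 0.185 at 24 h. A GC trend also marked 0 h replicate A, so the simulated rates need not hold for these libraries. Alternatives covered scaling (DESeq2 1.42.0 size factors, upper quartile, library size), filters, the tests of DESeq2, limma voom and glmTreat, the replicate letter as a block, and each library left out. A correction for GC content and transcript length, alone and with the block, was added after seeing the data. Figures were drawn with matplotlib 3.10.9.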

Results

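Messenger RNA was sequenced in V6.5 cells, a mouse embryonic stem cell line, before and after Cas9 was induced in stable lines carrying guide RNAs. The labels describe guides against Klf4 alone or against Klf2, Klf4 and Klf5 in tandem, and the sample titles carry the abbreviation TKO. Titles of the 24 h libraries also name a knockout of KLF4, and those of the 0 h libraries name WT ESCs. Which of these guides each library carried, and whether the 0 h cells carried any, is therefore uncertain. Cells grew on irradiated feeders in medium with 15% serum and 1000 U/ml LIF, with a MEK inhibitor (1 µM) and a GSK3 inhibitor (3 µM). Each group had 2 biological replicates, called A and B, and 46031578 to 52412844 counts per library. The comparison asks which transcripts differ 24 h after induction. Every 24 h library had also received doxycycline, so the drug, Cas9 cutting, loss of KLF protein and time share 1 contrast. If the 0 h cells were another line, that difference would share it too.

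The transcripts of the 3 genes named for the guides, Klf2, Klf4 and Klf5, were not past edgeR's test at 24 h, and 1 had an unadjusted p under 0.05. DESeq2's Wald test called 1 of them (Klf5, lower) and limma voom 0. Klf5 (chromosome 14, 99298691 to 99315036) went from 362.6 ± 96.5 to 220.8 ± 7.23 CPM (SD, n = 2), a log2 fold change of -0.72 (SE 0.17), with an adjusted p of 0.0567 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Klf4 (chromosome 4, 55527143 to 55532466) went from 294.2 ± 52.6 to 240.1 ± 6.17 CPM, a log2 fold change of -0.29 (adjusted p = 0.223 in the same edgeR test). Klf2 (chromosome 8, 72319033 to 72321656) went from 177.7 ± 76.7 to 149.9 ± 3.67 CPM, a log2 fold change of -0.25 (adjusted p = 0.58 in edgeR). Adjusted over the list alone, 1 of the 3 was lower, which was Klf5. The 0 h libraries differed from each other in Klf2 (231.9 CPM in A, 123.5 in B). Without 0 h replicate A the log2 fold change of Klf2 was 0.28 and that of Klf5 -0.42. Without 0 h replicate B those of Klf2, Klf4 and Klf5 were -0.63, -0.47 and -0.97. Here and below, a fit without 1 library assumes that the lone sample varies like the other group. Its p-values and counts of calls therefore do not measure the spread of the lone sample's group. With guides against Klf4 alone, Klf2 and Klf5 would not be targets. Small insertions and deletions need not change a transcript's level, and protein was not analysed here, so these values neither check the labels nor contradict them.

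**Figure D1:**
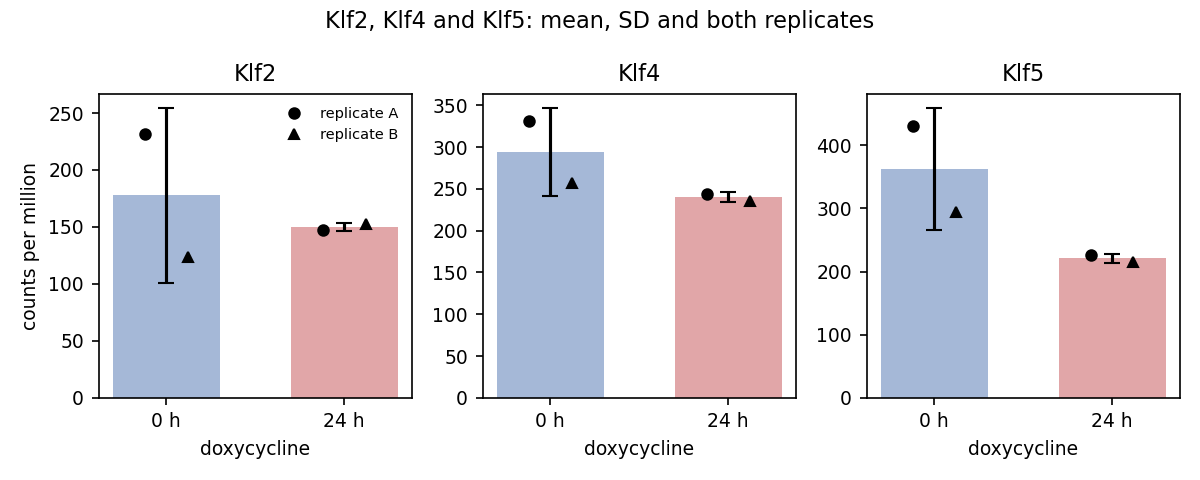
CPM of Klf2, Klf4 and Klf5 at 0 h and 24 h, where bars show the mean, whiskers the SD of 2 libraries, circles replicate A and triangles replicate B. For Klf2 the 24 h libraries (147.3 and 152.5 CPM) lie between the 0 h libraries (231.9 and 123.5 CPM).

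Across the transcriptome, 1225 of 18005 genes changed at 24 h (6.8%), 748 higher and 477 lower (61.1% higher). Of these, 584 changed at least 2-fold, 403 higher and 181 lower. At an unadjusted p under 0.05 there were 4642 genes. The 0 h replicate A stood apart from the other libraries. The SD of log2 differences between replicates was 0.356 at 0 h and 0.185 at 24 h, and the deviation of 0 h replicate A correlated with gene GC content (r = 0.581 across 14301 genes, which are not independent, against -0.257, -0.224 and -0.311 in the others). With the GC and length trend removed, 4668 genes were called, 1819 higher and 2849 lower (39.0% higher), and 1223 of the 1225 were among them in the same direction. The count was 6040 without 0 h replicate A, 9416 without 0 h replicate B, 563 without 24 h replicate A and 506 without 24 h replicate B.

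**Figure D2:**
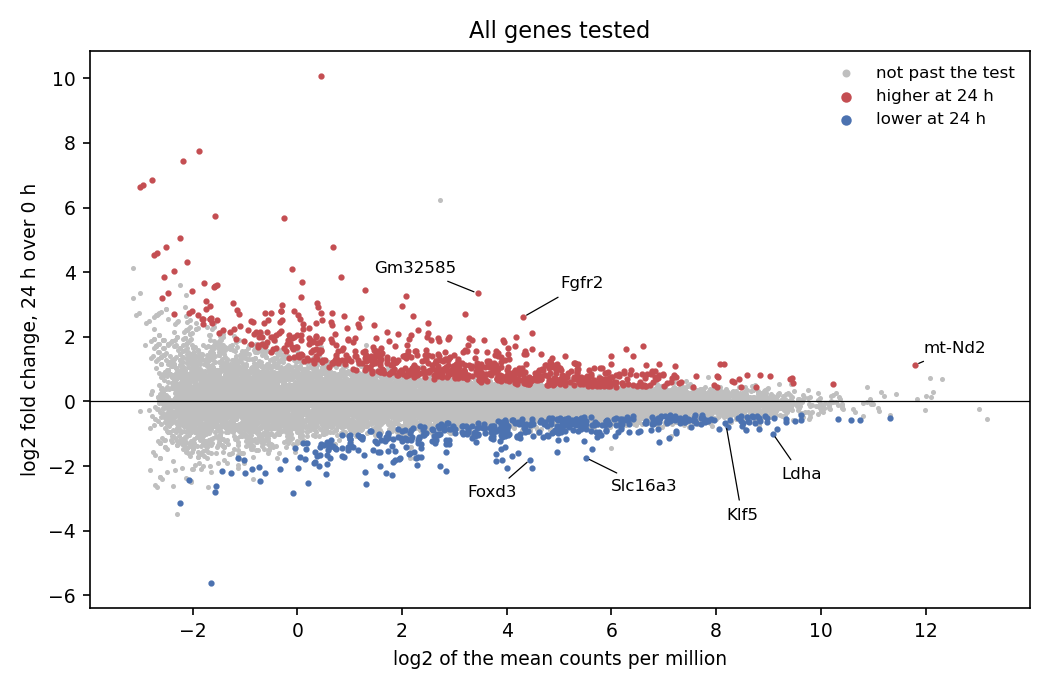
Log2 fold change of 24 h over 0 h against the log2 of the mean CPM for the 18005 genes tested, where red and blue points passed edgeR's test (adjusted p below 0.05). The 748 higher genes include Gm32585 and Fgfr2, and the 477 lower genes include Foxd3 and Slc16a3.

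**Figure D3:**
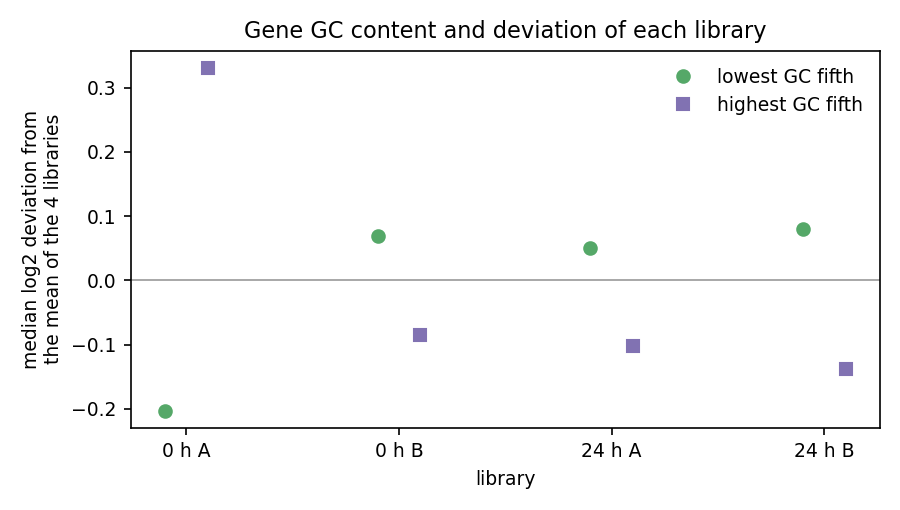
Median log2 deviation from the mean of the 4 libraries, per library, for the genes in the lowest quintile (circles) and the highest quintile (squares) of GC content. The highest minus the lowest quintile was 0.534 in 0 h replicate A and -0.154, -0.152 and -0.218 in 0 h replicate B and 24 h replicates A and B.

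The largest rises are given for genes past the test with a mean of at least 5 CPM and groups that do not overlap. The long noncoding RNA Gm32585 (chromosome 5, 125238314 to 125272815) rose from 1.959 ± 0.198 to 19.89 ± 1.19 CPM (SD, n = 2), a log2 fold change of 3.34 (SE 0.17, adjusted p = 0.00235 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fgfr2, a receptor for fibroblast growth factors, rose from 5.602 ± 0.515 to 34.12 ± 0.347 CPM. Its annotated span (chromosome 7, 130162451 to 133123350) overlaps many expressed genes, so its counts are uncertain. Fgg, a chain of fibrinogen, rose by 2.69 on the log2 scale, Zhx1 by 2.41, the protease inhibitor Serpine2 by 2.12 and Crabp2, which binds retinoic acid, by 2.12. Efnb2, a membrane ligand of Eph receptors, reached 29.12 ± 1.07 CPM from 7.268 ± 0.634. Efemp1, Ppp1r16b and Gpx6 rose by 2.00, 1.99 and 1.98. Zhx1 overlaps Gm29394 on the same strand, and its counts are uncertain too.

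By the same rule, with a mean of at least 5 CPM, Ceacam10 and Pou2f3 had the largest falls. Foxd3, a transcription factor of stem cells and neural crest, fell from 33.95 ± 9.2 to 9.756 ± 0.862 CPM (SD, n = 2; log2 fold change -1.80, SE 0.20, adjusted p = 0.00755 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Pou2f3 (chromosome 9, 43123939 to 43210369) fell from 36.33 ± 1.62 to 8.636 ± 0.367 CPM, and the caudal homeobox gene Cdx1 from 10.57 ± 2.78 to 2.637 ± 0.284 CPM. Ceacam10 had a log2 fold change of -2.15, the guidance cue Ntn1 -2.07, Cyp2s1 -1.83, the glutamate receptor subunit Grin1 -1.80, the semaphorin Sema3b -1.72 and Emp1 -1.68. Cyp2s1 and Grin1 each overlap a noncoding gene on the other strand, and their counts are uncertain. The size of some falls depended on 0 h replicate A, which carried the GC trend. Foxd3 was at 40.46 CPM in 0 h replicate A and 27.45 in B, and Grin1 at 28.62 and 17.96. Emp1 (23.32 and 29.36) and Ceacam10 (11.27 and 12.24) were higher in B. Genes called lower had a median GC content of 53%, against 49.4% for genes called higher.

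Targets of the tumour suppressor p53 rose as a group. Of 25 measured, 11 rose, 0 fell and 14 did not pass, and 13 rose and 1 fell adjusted over the list alone. By sign, 20 log2 fold changes were positive and 5 negative. Cdkn1a (0.09), Bax (-0.18) and Bbc3 (-0.72), chosen after their values were seen, were among the 14. Fas, a death receptor, rose from 0.6253 ± 0.0177 to 2.674 ± 0.00389 CPM (SD, n = 2), Cd80 from 3.667 ± 0.153 to 10.52 ± 0.563, the kinase gene Plk2 from 68.5 ± 1.35 to 124.0 ± 1.56 and the antiproliferative Btg2 from 112.1 ± 2.01 to 187.8 ± 0.898. The list's median log2 fold change was 0.35, with an adjusted p of 8.31e-08 in camera (limma) and adjusted p = 0.329 with an estimated correlation. The count of p53 targets that rose was 19 without 0 h replicate A (1 fell), 16 without 0 h replicate B (6 fell), 3 without 24 h replicate A and 4 without 24 h replicate B.

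Glycolysis and cholesterol synthesis genes fell as groups. Of 19 glycolysis genes, 9 fell and 10 did not pass, and 16 fell adjusted over the list alone. Ldha, which encodes lactate dehydrogenase A, fell from 721.4 ± 68.6 to 362.3 ± 3.52 CPM (SD, n = 2), the lactate transporter Slc16a3 from 70.16 ± 19.3 to 20.98 ± 0.84, Aldoc from 48.76 ± 6.66 to 21.53 ± 0.201 and Pfkp from 451.9 ± 20.8 to 283.2 ± 1.4. Pfkp overlaps Pitrm1 on the other strand, and its counts are uncertain. The glycolysis median was -0.58 on the log2 scale, with an adjusted p of 6.59e-12 in camera (limma) and adjusted p = 0.579 with an estimated correlation. Of 20 cholesterol synthesis genes, 8 fell and 12 did not pass, and 14 fell adjusted over the list alone. Insig1 fell from 122.2 ± 7.12 to 80.29 ± 0.751 CPM, Dhcr7 from 142.0 ± 16.4 to 91.81 ± 0.974 and Fdps from 18.75 ± 1.94 to 10.04 ± 1.96. Their median was -0.44, with an adjusted p of 1.75e-08 in camera (limma) and adjusted p = 0.329 with an estimated correlation. Without 0 h replicate A, 0 h replicate B, 24 h replicate A and 24 h replicate B in turn, edgeR's test called 18, 17, 3 and 3 glycolysis genes lower, and 18, 19, 2 and 0 cholesterol synthesis genes.

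Part of the pluripotency network fell. Of 19 naive pluripotency genes, 6 fell and 13 did not pass, and 6 fell adjusted over the list alone. Esrrb (0.01), Nanog (-0.29), Tfcp2l1 (-0.21) and Tbx3 (-0.26), chosen after their values were seen, were among the 13 (log2 fold changes). Tcl1 fell from 119.5 ± 13.7 to 62.06 ± 2.57 CPM (SD, n = 2), the nuclear receptor gene Nr0b1 from 73.44 ± 5.58 to 44.49 ± 0.728, Tdh, which encodes threonine dehydrogenase, from 269.7 ± 24.6 to 174.6 ± 2.26 and Prdm14 from 57.12 ± 1.23 to 40.91 ± 1.05. The list's median was -0.21 on the log2 scale, with an adjusted p of 0.00857 in camera (limma) and adjusted p = 0.579 with an estimated correlation. Without 24 h replicate A, camera's adjusted p was 0.0571, and 1 gene fell. Without 24 h replicate B 1 also fell, while 9 fell and 3 rose without 0 h replicate A, and 11 fell and 3 rose without 0 h replicate B. Among 14 general pluripotency genes, Pou5f1 (which encodes OCT4) fell from 767.2 ± 110 to 528.3 ± 1.28 CPM, Utf1 from 106.6 ± 32.9 to 55.73 ± 0.598 and L1td1 from 483.1 ± 32.7 to 310.6 ± 3.57, while Lin28a rose from 42.64 ± 1.38 to 60.6 ± 1.88. The other 10 did not pass, among them Sox2 (log2 fold change 0.07), chosen after its value was seen. Adjusted over the list alone, 2 rose and 4 fell. That list was not past camera (adjusted p = 0.367), but was without 0 h replicate A (0.0369). Of 17 genes of the formative and primed state, 4 fell (Foxd3, Tcf15, Pou3f1 and Dnmt3l) and 13 did not pass, and adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.192). Of 18 other KLF and SP factors, Klf8 fell from 50.11 ± 0.621 to 27.23 ± 0.942 CPM and Klf3 from 162.7 ± 24.5 to 103.0 ± 2.07, and 16 did not pass. With the GC and length trend removed, 6 of the 18 fell and 0 rose. Adjusted over the list alone, 2 fell (camera adjusted p = 0.0562, with 0.0273 after removal of the GC and length trend, 0.0267 without 0 h replicate A and 0.0238 without 0 h replicate B). Tdh, Pou5f1, Dnmt3l and Klf3 each overlap another gene (Aire in the case of Dnmt3l), and their counts are uncertain.

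**Figure D4:**
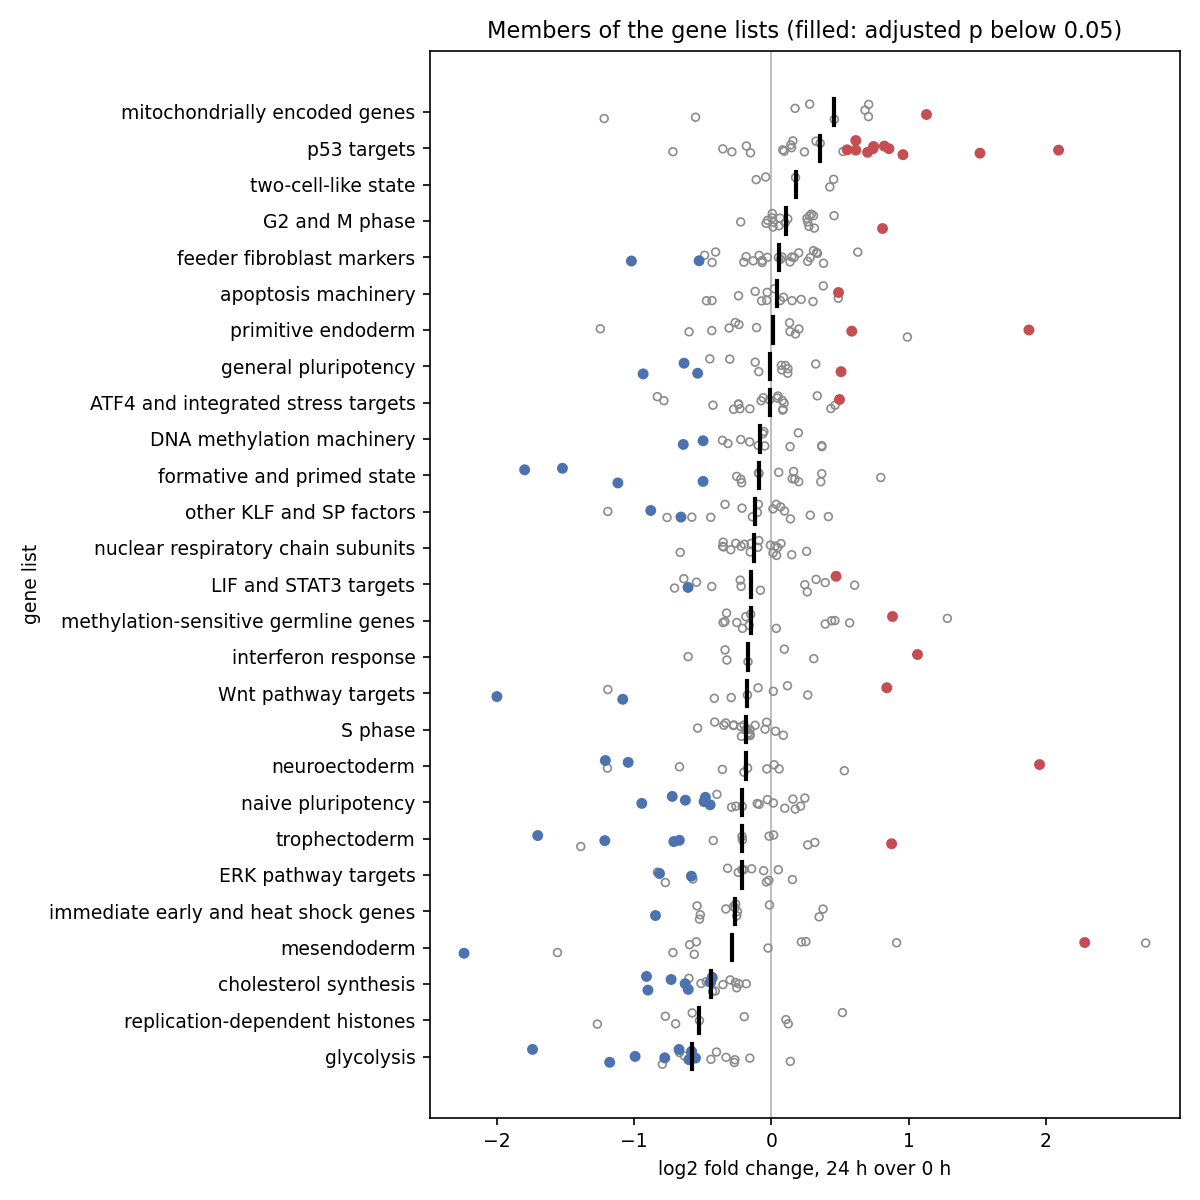
Log2 fold change of 24 h over 0 h for each measured member of 27 gene lists, where filled points passed edgeR's test over all genes and black lines mark list medians. Glycolysis genes have the lowest median (-0.58), and p53 targets (0.35) have 11 members past the test.

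Lineage markers changed in both directions, and no lineage list passed camera with all 4 libraries in the main settings. In mesendoderm (12 measured), Wnt3 rose from 0.3952 ± 0.14 to 1.927 ± 0.0356 CPM (SD, n = 2) and Lefty2 fell from 2.414 ± 0.416 to 0.5105 ± 0.124. Adjusted over the list alone, 1 rose and 2 fell, and the list's median was -0.29 and its mean 0.01 (camera adjusted p = 0.825, direction down). That median was 0.21 without 0 h replicate A, -0.41 without 0 h replicate B and 0.04 with the GC and length trend removed. In neuroectoderm (12 measured), Neurod1 rose from 3.96 ± 0.13 to 15.35 ± 0.841 CPM, and Tubb3 and Pou3f2 fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.538). In primitive endoderm (14 measured), Hnf4a and Lamb1 rose, as they did adjusted over the list alone, when 2 rose (camera adjusted p = 0.829). In trophectoderm (13 measured), Krt7 rose and Ly6a, Tead4, Krt19 and Tfap2a fell, the last chosen after its values were seen, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0636, and 0.00496 without 24 h replicate B). The counts of Neurod1, which overlaps Cerkl on the same strand, and of Tfap2a, which overlaps an antisense gene, are uncertain. Of the 5 measured two-cell-like genes, 0 passed edgeR's test, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 0 passed with DESeq2 or limma voom (camera adjusted p = 0.904).

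Of the signalling lists, targets of the ERK pathway were lower as a group in camera with the preset correlation, and those of Wnt and of LIF and STAT3 did not pass. Of 15 ERK pathway targets, Ccnd1, which encodes cyclin D1, fell from 137.1 ± 8.33 to 91.48 ± 1.81 CPM (SD, n = 2) and Ier3 from 8.34 ± 0.534 to 4.737 ± 0.0103, and 13 did not pass. Adjusted over the list alone, 4 fell. The list's median was -0.21 with a camera adjusted p of 0.0326, but adjusted p = 0.767 with an estimated correlation, 0.127 with the GC and length trend removed, 0.176 without 0 h replicate A, 0.0969 without 0 h replicate B and 0.106 without 24 h replicate A. Among 11 Wnt pathway targets, Tnfrsf19 rose from 50.91 ± 0.625 to 91.18 ± 0.494 CPM, and Cdx1 and Notum fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.165). Among 14 LIF and STAT3 targets, Lifr rose and the kinase gene Pim1 fell from 233.3 ± 21.4 to 153.0 ± 4.99 CPM, and 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.646, and 0.0238, lower, without 0 h replicate B). Of 14 genes of the DNA methylation machinery, Tet2 fell from 162.1 ± 10.2 to 103.8 ± 1.09 CPM and Dnmt3l also fell, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.409). Of 15 methylation-sensitive germline genes, Hormad1 rose, with 1 higher adjusted over the list alone (camera adjusted p = 0.838, direction up, with a median of -0.15 and a mean of 0.14). The germline median was 0.21 without 0 h replicate B, -0.04 without 24 h replicate A and -0.02 without 24 h replicate B. Ccnd1, Notum, Pim1 and Dnmt3l each overlap a gene on the other strand, and their counts are uncertain.

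In the main settings no S phase gene passed edgeR's test on its own (0 of 20, and 0 adjusted over the list alone). At an unadjusted p under 0.05, 6 were lower, with 2 lower in DESeq2 and 0 in limma voom. With the GC and length trend removed, edgeR's test called 13 of the 20 lower and 0 higher (camera adjusted p = 0.00235). The list's median in the main settings was -0.18 on the log2 scale. Its camera adjusted p there was 0.0326, and adjusted p = 0.767 with an estimated correlation. Mcm5, a subunit of the replicative helicase, was at 646.2 ± 93.8 and 485.0 ± 12.8 CPM (SD, n = 2), and Pcna at 157.5 ± 8.47 and 123.8 ± 4.79. Without 24 h replicate A the camera adjusted p was 0.0629, and without 24 h replicate B 0.0509. Without 0 h replicates A and B in turn, edgeR called 11 and 15 of them lower. Of 20 genes of G2 and M phase, Hmmr rose from 279.5 ± 62.5 to 489.3 ± 10.8 CPM, as it did adjusted over the list alone (1 higher). The list had a camera adjusted p of 0.102, and 0.767 with an estimated correlation. With the GC and length trend removed, 3 rose and 0 fell. The list's median was 0.11, with 0.095 without 0 h replicate A and 0.15 without 0 h replicate B.

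The background lists followed cell types and stresses that the contrast could also hold. Of 26 feeder fibroblast markers, Pdgfrb and Ccn2 fell and 24 did not pass, with 1 higher and 2 lower adjusted over the list alone (median 0.06, with -0.05 without 0 h replicate B, -0.03 without 24 h replicate B and 0.17 without 0 h replicate A, camera adjusted p = 0.974). Among 9 mitochondrially encoded genes, mt-Nd2 rose from 2237 ± 807 to 4880 ± 413 CPM (SD, n = 2), with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.143, and, higher, 0.00181 without 24 h replicate A and 1.91e-11 without 0 h replicate B). The ratio of mt-Nd2 to mt-Co1 was 0.176 and 0.224 at 0 h, and 0.649 and 0.652 at 24 h. That of mt-Nd1 to mt-Co1 rose by less, from 0.329 and 0.373 to 0.845 and 0.823. So did that of mt-Cytb to mt-Co1, from 0.285 and 0.309 to 0.714 and 0.719. These ratios were not part of the plan fixed in advance. Of 20 nuclear respiratory chain genes, 0 passed edgeR's test, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05. In DESeq2 1 was lower and in limma voom 0 (camera adjusted p = 0.177). The count of 0 depended on the setting, with 2 higher and 7 lower in edgeR once the GC and length trend was removed. The list's median was -0.12, and -0.19 without 0 h replicate B. Of 21 targets of ATF4 and the integrated stress response, Ddit3 rose, with 1 higher adjusted over the list alone (camera adjusted p = 0.975), and Ddit3 overlaps Mars, and Ccn2 Gm15270, on the other strand, so that their counts are uncertain. Of 7 interferon response genes measured, the RNA sensor gene Ddx58 rose from 10.61 ± 1.38 to 22.08 ± 1.28 CPM, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.974). Of 13 immediate early and heat shock genes, the chaperone gene Hspa8 fell from 740.6 ± 127.0 to 411.5 ± 1.18 CPM, with 1 lower adjusted over the list alone (camera adjusted p = 0.0379, with adjusted p = 0.579 with an estimated correlation, 0.127 with the GC and length trend removed, 0.0571 without 24 h replicate A and 0.0642 without 24 h replicate B). Of 16 apoptosis genes, Apaf1 rose, with 1 higher adjusted over the list alone (camera adjusted p = 0.829). Of 9 replication-dependent histone genes, 0 passed edgeR's test, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05, and 0 passed with DESeq2 or limma voom (camera adjusted p = 0.28).

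Of the 28 lists, 7 passed camera with the preset correlation, 1 higher and 6 lower. With an estimated correlation 0 passed (2 at an unadjusted p under 0.05). That version takes its degrees of freedom from the 4 libraries, so few lists could pass it. Fry, which tests whether a list's genes move on balance in 1 direction, passed 0 lists (6 at an unadjusted p under 0.05), and its mixed test, which takes either direction, passed 17.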

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

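The GC and length correction, alone and with the block, was chosen after seeing the data, and unless stated the cause of a change was not tested. The main counts were 1225 genes, 748 higher, 477 lower and 584 at least 2-fold. With no filter on low counts there were 2589 (1230 higher, 1359 lower) and with DESeq2's Wald test 1901 (958 lower). By glmTreat at 1.5-fold, which tests a larger change, there were 153 (118 higher, 35 lower, 153 at least 2-fold). The replicate letter as a block gave 3253 (1658 higher, 1595 lower, 960 at least 2-fold), with a correlation of 0.198 between same-letter deviations, and 2 pairs do not establish a pairing. The GC and length correction gave 4668 (1819 higher, 2849 lower), and with the replicate block 5418 (2070, 3348, and 915 at least 2-fold). Leaving out 1 library left the lone sample assumed to vary like the other group, and gave 506 to 9416 genes, 338 to 4352 higher, 168 to 5064 lower and 471 to 1440 at least 2-fold. All 1225 genes kept their sign in every setting with all libraries that tested them. Klf5 passed edgeR's threshold with DESeq2 size factors (log2 -0.71), no filter (-0.73), DESeq2's Wald test (-0.72), the replicate block (-0.69), the GC and length correction (-0.82) and both together (-0.78). Klf4 passed with the GC and length correction (-0.23, with the block -0.22), while Klf2, which did not pass, turned to 0.07 and 0.08. Leaving out 1 library gave -0.63 to 0.28 for Klf2, whose sign turned without 0 h replicate A (0.28), -0.47 to -0.10 for Klf4 and -0.97 to -0.42 for Klf5. The same gave list medians of -0.63 to -0.10 for Klf2, Klf4 and Klf5 together, -0.25 to -0.16 for naive and -0.083 to -0.017 for general pluripotency, -0.26 to -0.12 for other KLF and SP factors, -0.47 to -0.23 for trophectoderm, -0.41 to -0.032 for ERK, -0.34 to 0.078 for LIF and STAT3 targets, -0.26 to -0.13 for S phase and 0.086 to 0.15 for G2 and M phase. Of lists, other KLF and SP factors passed camera with no filter (-0.14), the block (-0.11), the correction (-0.22) and both (-0.22), trophectoderm with no filter (-0.44) and the block (-0.21), G2 and M phase with limma voom (0.11) and the block (0.11), and mitochondrially encoded genes with no filter (0.66) and the block (0.47). ERK targets (-0.28, -0.28) and immediate early and heat shock genes (-0.24, -0.24) no longer passed with the correction or with both. With an estimated correlation and with fry, which leave medians as they were, naive pluripotency (-0.21), p53 (0.35), ERK (-0.21), cholesterol synthesis (-0.44), glycolysis (-0.58), S phase (-0.18) and immediate early and heat shock genes (-0.27) no longer passed.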

Other observations

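The lists of imprinted genes and HIF targets, the genes Pvalb, Il9r and Gm28437, the tests without 0 h replicate A, of tandem paralogs and of calls kept after the GC and length correction were chosen only after results had been seen. The imprinted and HIF lists were written after 180 changed genes had been looked through, so each is given first without the members already seen, and the number of themes that were looked at and dropped is not known.

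Imprinted genes, which are expressed from 1 parental copy, and targets of the hypoxia-inducible factor HIF outside the glycolysis list had medians of opposite sign, with most members of each not past the test. Of 31 imprinted genes measured, leaving out H19, 8 rose and 0 fell in edgeR's quasi-likelihood test, and 23 did not pass. The list lacked Dio3, an imprinted gene next to Mirg among the genes tested, named after its value was seen. Dio3 passed the test and fell (log2 fold change -1.98), so the count of 0 and the list's tests hold for the listed genes only. Peg3 went from 77.14 ± 2.64 to 140.2 ± 0.111 CPM (SD, n = 2), Meg3 from 89.07 ± 1.98 to 142.8 ± 4.21 and Impact from 73.91 ± 3.89 to 112.5 ± 0.653. Rian and Gys1 each overlap another gene, and their counts are uncertain. Meg3, Rian and Mirg are neighbours, as are Peg3 and Usp29, so the members are not independent. The median was 0.18, with a camera adjusted p of 0.0104 over 2 lists and p = 0.086 with an estimated correlation. With the GC and length trend removed, 10 rose and 7 fell, with a median of 0.05. Without 0 h replicate A 12 rose and 6 fell, and without 0 h replicate B 13 rose and 8 fell. H19 itself went from 1.198 ± 0.0944 to 5.356 ± 0.623 CPM. Of 22 HIF targets, leaving out Ndrg1, Egln1, Ak4 and Gys1, 3 fell (Kdm3a, P4ha2 and Anxa2) and 0 rose. Their median was -0.17, with a camera adjusted p of 0.0184, p = 0.122 with an estimated correlation, and an adjusted p of 0.182 without 0 h replicate B. Without 0 h replicates A and B in turn, 10 and 10 of them fell, and 4 and 3 rose. With the 4 members seen first put back, 7 of 26 fell and camera's adjusted p was 2.22e-05, a value that those members were chosen to give in part. With an estimated correlation camera's p for these 26 was 0.039, before adjustment.

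Transcripts with 0 counts in both 0 h libraries passed edgeR's test for 6 genes. Pvalb, a calcium-binding protein of muscle and neurons, had 126 and 138 counts at 24 h (2.742 ± 0.292 CPM, SD, n = 2), at least 46.2-fold higher than a floor of 3 counts per 0 h library. Il9r, the interleukin 9 receptor, had 6 and 5 counts at 0 h and 152 and 148 at 24 h. The pseudogene Gm28437 had 1221 counts in 24 h replicate B, against 2, 15 and 7 in 0 h A, 0 h B and 24 h A. Its high value rests on 1 library, and it did not pass edgeR's test (adjusted p = 0.112).

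Genes changed at 24 h could reflect other cells, the drug or the libraries as well as KLF loss. A different share of feeder fibroblasts is argued against, since of 25 feeder markers with at least 1 CPM 13 were higher and 12 lower, 52% going the more common way. A GC or length trend as the whole source of the calls is argued against by 1223 of the 1225 genes being called again with the trend removed; the bounds written before the test, a fall of the count or a count within 1.5 times, were both missed when it rose 3.81 times to 4668, so that count decides nothing. Doxycycline acting on mitochondrial translation cannot be told apart from KLF loss, since every 24 h library received the drug. The ATF4 list's camera adjusted p of 0.975 met the bound set in advance for excluding it. That list is an indirect measure whose members went both ways, and not passing camera does not show that the drug had no effect. The ratio of mt-Nd2 to mt-Co1, which the bound and the plan left out, went from 0.176 and 0.224 at 0 h to 0.649 and 0.652 at 24 h. The ratios of mt-Nd1 and mt-Cytb to mt-Co1 rose by less. With 2 against 2 libraries there are too few splits to test for chance. The other 2 splits gave 0 calls (58 and 42 genes at an unadjusted p under 0.05). Each of them mixes 0 h and 24 h in both groups, so the difference between times enters the spread. Few calls follow from that design, and they decide nothing about chance.

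The p53 and glycolysis lists were tested against the GC and length trend and against the 0 h library that stands apart. With the trend removed, the p53 median was 0.34 (camera adjusted p = 3.03e-10) and the glycolysis median -0.48 (adjusted p = 3.66e-16). Without 0 h replicate A they were 0.44 and -0.44. Both technical explanations are argued against as the whole cause. Neither list passed camera with an estimated correlation (adjusted p = 0.329 and 0.579). The estimate was -0.031 for p53, under the preset 0.01, and 0.479 for glycolysis. A higher correlation therefore does not account for the loss of the p53 call. That version takes its degrees of freedom from the 4 libraries, so few lists could pass it, and it decides neither call. DNA cutting by Cas9, which may raise p53 targets with any guide, stays open, as a control guide was not analysed here.

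Neighbouring genes changed together. Of 111 adjacent, non-overlapping pairs with both genes changed, 92 changed in the same direction (82.9%), 58 pairs higher and 34 lower, against a median of 52.2% and an upper limit of 63.9% (of the central 95%) in 10000 shuffles of gene order (1-sided permutation p = 0.0001, the smallest they can give). Read-through between neighbours is argued against by 79.4% among 34 pairs on opposite strands and over 10 kb apart (upper limit 73.7%) and shared GC content by 65.0% among 1150 pairs with the trend removed (55.4%). Reads shared by tandem paralogs cannot be told apart from shared regulation: 101 pairs whose symbols differ in their first 3 letters gave 81.2%, but setting aside 10 of the 111 pairs could not have brought the share to its limit of 64.6%. Shared regulation of neighbours is consistent with these values and remains a hypothesis, found and tested on the same libraries.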
